A study of Homo sapiens with 12 samples.

How the data were processed

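RNA from 12 samples of KYSE150 cells was hybridised to Affymetrix expression arrays, 1 array per sample. Per the labels, cells were transfected with plasmids that express a short hairpin RNA, put under puromycin at 2 µg/ml from 24 h after transfection and harvested after 72 h of selection, and total RNA was biotin-labelled with a whole transcript kit. The labels give 4 groups of 3 arrays: scrambled hairpin, JMJD2C hairpin, JMJD2A hairpin, and both. The design text says that the experiment was done in triplicate, and whether the replicates come from separate cultures is not stated, so p-values measure the spread between these samples, which may in part be technical. No 2 arrays held identical values.

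The deposited values were used as they are: the authors' table holds 1 log2 value per probe set and array, with array minima between 3.73 and 3.82 and maxima between 14.79 and 14.86. The log2 scale was read from these values. The submitters' processing notes name the affy package. Background correction, normalization and summary method are not given in the sources used here. Medians differ by little between arrays while the quartiles do not match exactly, so a shift in spread between groups was left in place and could move bright and dim genes in opposite directions.

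The table has 22277 probe sets, of which 62 are controls. Gene symbols came from the platform annotation: 19070 probe sets had 1 symbol, 1043 several and 2164 none. Entrez identifiers of 19052 probe sets were found in a current RefSeq gene table, and 0 symbols had to be changed through it. Probe sets with several symbols or none were not named. For each gene the probe set with the highest mean over all arrays was used, which gave 11963 genes from 19064 probe sets (4310 genes had more than 1). No filter on dim genes was applied.

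All 12 arrays were fitted in 1 linear model with 4 group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation (8 residual and 6.29 prior degrees of freedom). The 7 contrasts were each hairpin or both against the control, both against each single hairpin, the single hairpins against each other, and the interaction. Each used limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, with no fold minimum. Every adjusted p of a gene comes from this test. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so single genes rest on the model's pooled spread. Tested on simulated data for shJMJD2C against the control (11963 genes, 50 changed at each size), it recovered 52% of 1.25-fold, 90% of 1.5-fold and 100% of 2-fold changes, with 4 false calls. The simulated noise was independent between genes and few genes changed, unlike in the real arrays, so these rates may not hold there.

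These choices were made before the data were examined: the groups, the contrasts, the test, 26 gene lists, the rule for named genes and most alternatives. Named genes are KDM4C and KDM4A, then the 10 largest rises and 10 largest falls against the control (5 and 5 in the other contrasts) among called genes whose arrays do not overlap between the groups. The overlap condition was not set for the interaction. From a list, up to 4 called members with the largest changes are named. Genes without an official symbol and small non-coding RNAs were counted but not named. KDM4D, and KDM4B with shJMJD2C, were named outside this rule, after the values were seen, as relatives of the targets. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists, and again with an estimated correlation. Members missing from the annotation used were not analysed here. Counts "adjusted over the list alone" apply the adjustment to the members only.

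To show what shared controls do, 100 sets of unchanged groups were simulated against simulated controls with each gene's moderated spread. Replicate numbers are shared between groups but the labels do not say that they mark a shared day, so no block was used in the model above. The rule set here for a pairing was that deviations from the group means correlate above 0.1 for every shared number. Of the 6 pairs of groups, 1 met it: the 3 values were between 0.101 and 0.130 for shJMJD2C and the double knockdown. The other 5 pairs of groups did not meet it. Arrays with different numbers correlated from -0.364 to 0.338 over all groups, so values this small cannot show that the numbers mark a pairing. Alternatives were quantile normalization, centring on medians, brighter genes only, other uses of the probe sets, trend and robust moderation, the groups of the contrast alone, a minimum of 1.5-fold, a replicate block, array weights and leaving out each array. Chosen after the data were seen were a loess correction of each array against the mean array, the 28S ribosomal RNA level as a covariate, and the fit without the arrays with outlying control probe sets. Slopes of one change on another were fitted through the origin, with a jackknife over arrays within groups.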

Results

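The series measured gene expression in KYSE150 cells, a human oesophageal squamous carcinoma line, after knockdown of the histone demethylases JMJD2C (gene KDM4C) and JMJD2A (gene KDM4A). Both enzymes remove methyl groups from lysine 9 and lysine 36 of histone H3. The 12 arrays fall into 4 groups of 3: a scrambled hairpin as control, a hairpin against JMJD2C, a hairpin against JMJD2A, and both hairpins together, called the double knockdown here. The design therefore asks what each hairpin changes against the control, what each adds to the other, and whether the joint change equals the sum of the single changes. Signals are on the log2 scale. Array medians ran from 6.10 to 6.14 and the highest signals from 14.79 to 14.86, and replicate arrays correlated across all probe sets with r between 0.995 and 0.998. In total 11963 genes were tested in each comparison. The number of arrays limits the precision: the typical standard error (SE) of a log2 change was 0.08 between groups and 0.12 for the interaction.

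The hairpins lowered their targets in every sample that carried them. KDM4C signal was 7.31, 7.25 and 7.04 in the 3 control arrays and 5.67, 5.73 and 5.76 in the shJMJD2C arrays. Its mean fell by 1.48 on the log2 scale (SE 0.09, adjusted p = 5.23e-09), which leaves 35.8% of the control level. In the double knockdown the KDM4C signals were 5.93, 5.72 and 5.86, a fall of 1.37 that leaves 38.8%. With the JMJD2A hairpin alone KDM4C stood at 7.21, 6.98 and 7.15, a difference of -0.09 (SE 0.09, adjusted p = 0.543). KDM4A signal was 7.25, 7.15 and 7.26 in the control and 6.10, 5.65 and 6.23 with shJMJD2A, so that its mean fell by 1.23 (SE 0.11, adjusted p = 2.06e-06) to 42.7% of the control level. The double knockdown arrays read 6.63, 6.48 and 6.54 for KDM4A, 62.9% of the control level. With the JMJD2C hairpin alone KDM4A rose by 0.37 (SE 0.11, adjusted p = 0.0163), with signals of 7.48, 7.69 and 7.59. Against that higher level the double knockdown kept 48.7% of KDM4A, a fall of 1.04 (adjusted p = 0.000263). The rise of KDM4A with shJMJD2C was not called without control replicate 2 (0.33, adjusted p = 0.058) or without shJMJD2C replicate 2 (0.31, adjusted p = 0.0653). Over all 23 other settings its adjusted p ran from 0.00114 to 0.0653.

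Other probe sets of the same genes did not all behave alike. The other KDM4A probe set fell by 1.02 with shJMJD2A and by 0.70 in the double knockdown. Its difference of 0.24 with shJMJD2C did not pass (adjusted p = 0.0702 over all probe sets). A dim KDM4C probe set with a control mean of 4.88 ± 0.04 (SD, n = 3) showed differences of 0.14 in shJMJD2C and 0.09 in the double knockdown that did not pass the test. KDM4B, a close relative of both targets, fell by 0.45 with shJMJD2C (SE 0.10, adjusted p = 0.00211), by 0.36 with shJMJD2A (SE 0.10, adjusted p = 0.0203) and by 0.68 in the double knockdown (SE 0.10, adjusted p = 8.52e-05). Its fall with shJMJD2A was not called without control replicates 1 and 3 (0.35 each, adjusted p = 0.052 and 0.0601) or without shJMJD2A replicates 1 and 2 (0.33 and 0.36, adjusted p = 0.0659 and 0.053), and over all 23 other settings its adjusted p ran from 0.00718 to 0.188. One more KDM4B probe set fell by 0.52 with shJMJD2C and by 0.65 in the double knockdown, with a difference of -0.02 in shJMJD2A, and the remaining 3, with control means of 5.43, 5.82 and 5.92, did not pass. KDM4D, named here as a relative of the targets and not by the rule, was at 4.58 ± 0.03 (SD, n = 3) in the control and did not pass the test in the double knockdown (difference 0.01).

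**Figure D1:**
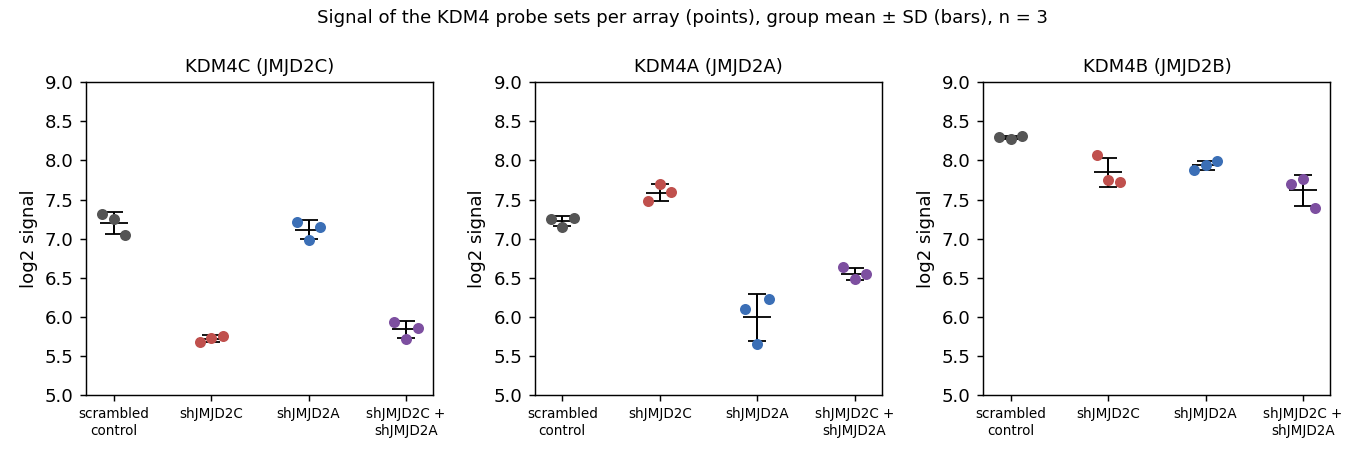
Log2 signal of the KDM4C, KDM4A and KDM4B probe sets used in the tests, for each of the 12 arrays (points) with the group mean and SD (bars, n = 3). The 6 arrays with the JMJD2C hairpin lie between 5.67 and 5.93 for KDM4C, and the other arrays between 6.98 and 7.31.

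Knockdown of JMJD2C alone moved the largest number of genes of the 3 comparisons against the control. This order did not hold with the 28S level as a covariate, a setting chosen after the data were seen. There 4003 genes were called with shJMJD2C and 4059 in the double knockdown. All 34 measured mitotic genes fell, with a median log2 change of -0.94, and 13 of 22 replication-dependent histone genes rose. The largest rise was that of MMP12, a matrix metalloprotease, at 2.89 (SE 0.12, 7.41-fold, n = 3 arrays per group). FN1, which encodes fibronectin, rose by 2.39 (SE 0.07, 5.25-fold), and IL1A, an inflammatory cytokine, fell by 2.25 (SE 0.12). At an adjusted p below 0.05, 2885 genes rose and 2800 fell, and 525 and 1209 of these did so by at least 1.5-fold.

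Among the 10 largest rises with shJMJD2C were also the histone H4 gene H4C8 (2.46), the squamous protease inhibitor SERPINB13 (2.34), TMEM45A (2.30), the secreted protease ADAMTS1 (2.22), the autophagy gene GABARAPL1 (2.02), TXNL4B (1.98), the basal keratin KRT14 (1.95) and the semaphorin and VEGF co-receptor NRP1 (1.93). SEs of these changes lay between 0.06 and 0.12. The 10 largest falls held SHLD2, a subunit of the shieldin DNA repair complex (-2.08), the ETS factor ELK3 (-2.07), the calcineurin subunit PPP3CB (-2.02), the cilium transport gene IFT57 (-2.02), the spindle-associated hyaluronan receptor HMMR (-2.01), the RNA-binding IGF2BP3 (-1.96), the centrosome gene CEP63 (-1.94), the Golgi mannosidase MAN2A1 (-1.92) and the protease inhibitor SERPINB1 (-1.87).

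The mitotic list, which includes cyclins, kinesins and spindle checkpoint genes, fell as a whole (camera adjusted p = 4.48e-20, and adjusted p = 0.0389 with an estimated correlation). Its 34 of 34 members also passed when adjusted over the list alone, among them DLGAP5 (-1.79, SE 0.07), the checkpoint kinase BUB1 (-1.61, SE 0.07) and topoisomerase TOP2A (-1.55, SE 0.09). E2F targets and DNA replication genes fell in 24 of 35 cases, none rose and 11 did not pass, and 24 also passed when adjusted over the list alone (camera adjusted p = 1.24e-08, and adjusted p = 0.0389 with an estimated correlation). Examples were the replication factors GINS1 (-1.17, SE 0.07) and MCM10 (-1.10, SE 0.06) and the primase subunit PRIM1 (-1.06, SE 0.06). Histone genes moved the other way: 13 rose, none fell and 9 did not pass, the counts adjusted over the list alone being the same (camera adjusted p = 0.000195, and adjusted p = 0.0389 with an estimated correlation). H2BC21 rose by 1.48 (SE 0.10), H4C5 by 1.14 (SE 0.13) and the linker histone H1-2 by 1.00 (SE 0.06). The histone call was lost when only the brighter genes were tested, 4 of 22 members (adjusted p = 0.133), with a median of 0.65 there.

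Factors of H3K9 methylation and heterochromatin fell in 12 cases, rose in 3 and did not pass in 5 of 20, with 13 lower and 3 higher when adjusted over the list alone (camera adjusted p = 0.0177, but adjusted p = 0.0826 with an estimated correlation). The chromatin remodeller ATRX fell by 1.67 (SE 0.12), the silencing factor TASOR by 1.14 (SE 0.07) and the heterochromatin protein gene CBX3 by 0.93 (SE 0.07), whereas the methyl-CpG binding MBD1 rose by 0.88 (SE 0.06). NRF2 targets, the genes of the oxidative stress response, rose in 13 cases, fell in 3 and did not pass in 5 of 21, with 14 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0177, but adjusted p = 0.139 with an estimated correlation). The detoxifying hydrolase EPHX1 rose by 1.09 (SE 0.08), UGDH by 0.92 (SE 0.08) and the haem oxygenase HMOX1 by 0.92 (SE 0.06).

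The ribosomal RNA and spread of the arrays moved with the same hairpin. The middle 28S ribosomal RNA control probe set averaged 11.97 over the 6 arrays with the JMJD2C hairpin and 11.34 over the 6 without it (exact permutation test, two-sided p = 0.00216, the smallest it can give with 924 arrangements). The interquartile range of the array was 3.42 with and 3.62 without that hairpin (exact permutation p = 0.00216). Along signal level, the median change in shJMJD2C was 0.16 among dim genes (group 4 of 10 by mean signal) and -0.16 among brighter ones (group 7 of 10). The H3K9 list was no longer called after quantile normalization, a loess correction for signal or among the brighter genes alone, with an adjusted p of up to 0.266 over its settings, but its median stayed between -0.46 and -0.31 in all of them.

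The other lists did not stand out with shJMJD2C, though many of their members changed. JmjC histone demethylases rose in 4 and fell in 5 of 20 cases: besides KDM4C, PHF2 fell by 0.73 and KDM5A by 0.70, and KDM3A rose by 1.07. Of the 15 factors of H3K4 methylation and CpG islands, 4 rose and 4 fell, with a median of 0.09 and a mean of -0.05. HIF targets rose in 8 and fell in 6 of 28 cases, with the MYC antagonist MXI1 at 1.64 (SE 0.06) and the mitophagy gene BNIP3 at -1.46 (SE 0.12). Basal squamous genes rose in 8 and fell in 7 of 22 cases, with KRT5 at 1.35 (SE 0.11) and the integrin ITGB4 at -1.01 (SE 0.10). Keratinocyte differentiation genes rose in 7 and fell in 2 of 27, with filaggrin FLG at 1.32 and the envelope protein PPL at -1.09. Mesenchymal and matrix genes rose in 13 and fell in 5 of 33. Unfolded protein response and ATF4 targets rose in 11 and fell in 8 of 29, led by the chaperone DNAJB9 at 1.80 (SE 0.07). MYC itself rose by 1.08 (SE 0.08), whereas its targets and ribosome biogenesis genes rose in 10 and fell in 8 of 22 cases including MYC. Apoptosis regulators rose in 9 and fell in 7 of 25, with the apoptosome gene APAF1 at -1.72 (SE 0.10). The 20 measured p53 targets rose in 4 and fell in 5 cases, with GDF15 at 1.04. Cholesterol synthesis genes rose in 8 and fell in 5 of 18, and oxidative phosphorylation genes rose in 4 and fell in 10 of 27. Haematopoietic and endothelial markers, fixed as a check for other cell types, rose in 6 of 17 cases and none fell, or in 4 when adjusted over the list alone, with a median of 0.20, or 0.10 after quantile normalization and after the loess correction, and CD14 at 0.54 (SE 0.08), and the list was not called (camera adjusted p = 0.111). Interferon-stimulated genes rose in 4 and fell in 11 of 27, NF-kB and inflammatory cytokine genes rose in 9 and fell in 2 of 25, and immediate early genes rose in 12 and fell in 10 of 30. The neighbours of KDM4C rose in 1 and fell in 4 of 14, KRAB zinc finger genes rose in 6 and fell in 5 of 29, Notch and Wnt targets rose in 4 and fell in 2 of 17, RNA interference genes rose in 3 and fell in 1 of 11, and cancer-testis antigens rose in 1 and fell in 2 of 18.

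**Figure D2:**
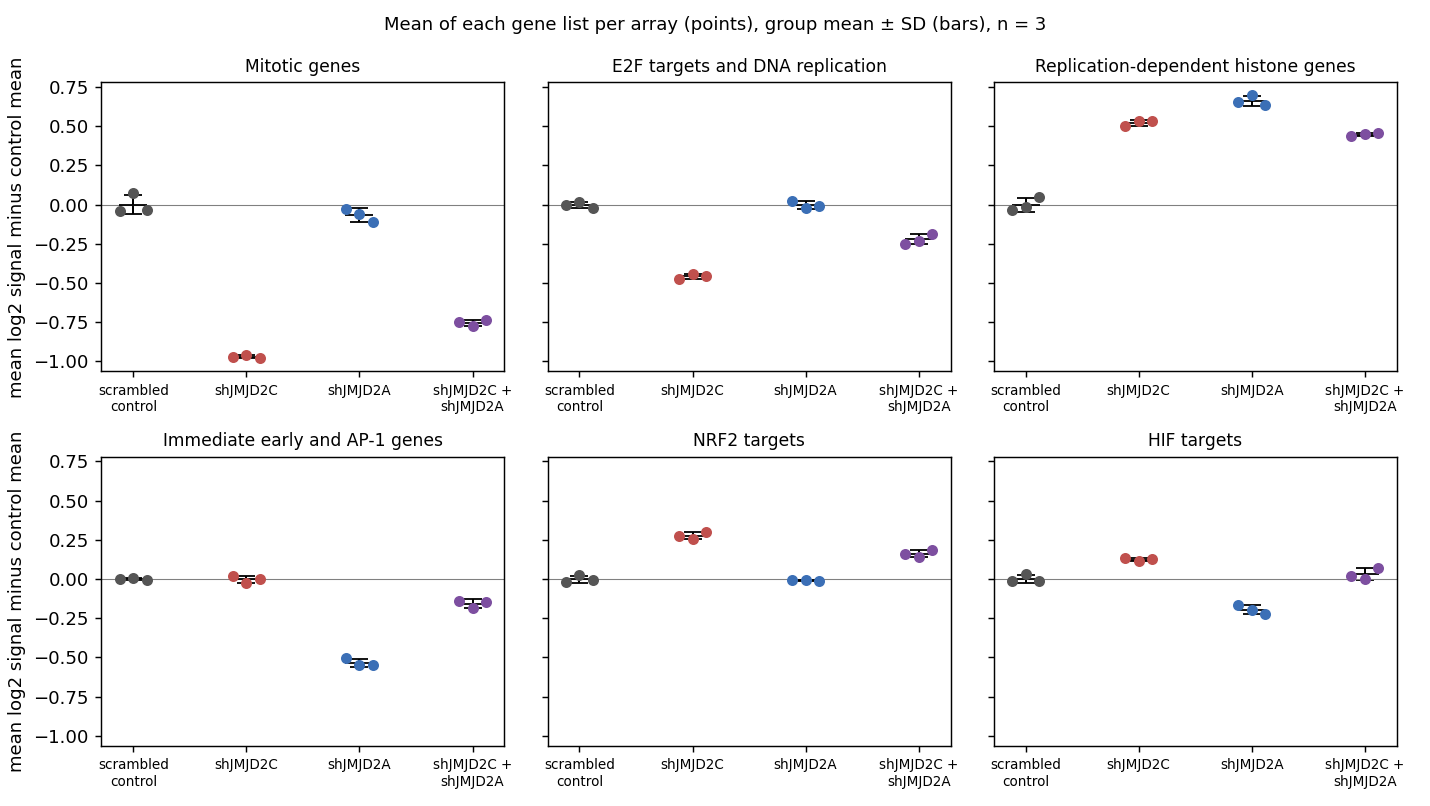
Mean log2 signal of 6 gene lists on each of the 12 arrays after subtracting the control mean (points), with group mean and SD (bars, n = 3). The mitotic list lies at -0.97 with shJMJD2C, at -0.75 in the double knockdown and at -0.07 with shJMJD2A, and the immediate early list at -0.53 with shJMJD2A.

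Knockdown of JMJD2A alone changed fewer genes than that of JMJD2C, and histone genes rose with it as well. Immediate early and AP-1 genes, which respond to growth factor signals, fell in 19 of 30 cases and none rose. CCN2, a matricellular growth factor, fell by 3.39 (SE 0.06, n = 3 arrays per group), the largest change in the comparison, and the ETS factor ELK3 fell by 3.28 (SE 0.12). HMGA2, a chromatin architectural factor, fell by 2.74 (SE 0.07). Filaggrin, FLG, a protein of the cornified layer, rose by 2.32 (SE 0.13, 4.98-fold). In all, 1207 genes rose and 1439 fell, 189 and 398 of them by at least 1.5-fold.

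The 10 largest rises with shJMJD2A included the linker histone H1-2 (2.08), the basal keratin KRT5 (2.02), the matrix protein tenascin C, TNC (1.97), SERPINB13 (1.94), the alkaline phosphatase ALPP (1.92), the histone genes H2BC21 (1.78), H2AC6 (1.72) and H4C8 (1.71), and KCTD9 (1.68). Their SEs lay between 0.06 and 0.11. The 10 largest falls also held the RNA export gene NXT2 (-2.28), the glycosyltransferase GALNT3 (-2.23), the adducin ADD3 (-2.22), IL1A (-1.92), EFCAB14 (-1.77), the secreted factor FAM3C (-1.75) and transglutaminase TGM2 (-1.74).

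The fall of the immediate early list passed both versions of the set test (camera adjusted p = 1.52e-12, and adjusted p = 0.0017 with an estimated correlation), and 19 members passed when adjusted over the list alone. EGR1 fell by 1.42 (SE 0.10), the growth factor HBEGF by 1.27 (SE 0.08) and the AP-1 subunit FOSL1 by 1.04 (SE 0.12). Replication-dependent histone genes rose in 13 of 22 cases, with 9 not passing, and in 14 when adjusted over the list alone (camera adjusted p = 7.8e-12, and adjusted p = 0.0021 with an estimated correlation). H2BC5 rose by 1.58 (SE 0.07). HIF targets, the genes of the hypoxia response, fell in 11 cases, rose in 1 and did not pass in 16 of 28, with 11 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00186, but adjusted p = 0.125 with an estimated correlation). The glycolytic hexokinase HK2 fell by 0.94 (SE 0.08) and the glucose transporter SLC2A3 by 0.88 (SE 0.09).

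Mitotic genes were not called as a list with shJMJD2A: 5 rose, 6 fell and 23 did not pass, with HMMR at -0.97 (SE 0.09) and CDK1 at -0.82 (SE 0.07). Interferon-stimulated genes fell in 7 and rose in 2 of 27 cases, with RSAD2 at -1.57 (SE 0.10) and OAS3 at -1.34 (SE 0.09). Keratinocyte differentiation genes rose in 6 and fell in 2 of 27, with the epithelial factor ELF3 at 1.08 (SE 0.08). Basal squamous genes rose in 9 and fell in 6 of 22, with KRT15 at 1.06 (SE 0.08) and the integrin ITGA6 at -1.06 (SE 0.08). Notch and Wnt targets rose in 4 and fell in 3 of 17, with CD44 at -1.44 (SE 0.07). Zinc finger genes of the KRAB class on chromosome 19 rose in 1 and fell in 4 of 29. RNA interference genes rose in 4 and fell in 2 of 11, with DICER1 at 0.95 (SE 0.15), and cancer-testis antigens rose in 2 and fell in 1 of 18, with TEX14 at 1.12 (SE 0.10). E2F and replication genes rose in 7 and fell in 7 of 35, with a median of 0.09 and a mean near 0. The 17 haematopoietic and endothelial markers did not pass in any case. None of these lists passed the set test.

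In the double knockdown the changes followed those of shJMJD2C. Mitotic genes fell in 31 of 34 cases, with a median of -0.75, and TMEM45A (2.42, SE 0.06), the secretory granule protein SCG2 (2.32, SE 0.12) and MMP12 (2.14, SE 0.12) showed the largest rises. ELK3 (-2.67, SE 0.12), IL1A (-2.60, SE 0.12) and IGF2BP3 (-2.11, SE 0.06) showed the largest falls (n = 3 arrays per group). Altogether 2318 genes rose and 2598 fell against the control, 348 and 931 of them by at least 1.5-fold.

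Further large rises in the double knockdown were those of H4C8 (2.08), FN1 (1.99), ADAMTS1 (1.91), the activin antagonist follistatin, FST (1.82), FLG (1.79), NRP1 (1.79) and SERPINB13 (1.74). Further large falls were those of ADD3 (-2.07), MAN2A1 (-1.91), EFCAB14 (-1.90), the sterol transfer gene OSBPL8 (-1.87), the phospholipase PLA2G12A (-1.78), CEP63 (-1.77) and RHOBTB3 (-1.75).

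For the double knockdown 6 lists passed the set test with the preset correlation, and none with an estimated one. Mitotic genes (camera adjusted p = 1.18e-18, but adjusted p = 0.0608 with an estimated correlation) had 32 lower members when adjusted over the list alone, led by HMMR (-1.69, SE 0.09) and BUB1 (-1.28, SE 0.07). The 28S signal moved with this list as it did with shJMJD2C alone, at 11.87 ± 0.05 (SD, n = 3) against 11.40 ± 0.29 in the control. Histone genes rose in 11 of 22 cases, or 14 when adjusted over the list alone (adjusted p = 0.0608 with an estimated correlation), with H2AC17 at 1.07 (SE 0.13). E2F and replication genes fell in 18 of 35 cases, and 18 also when adjusted over the list alone (adjusted p = 0.158 with an estimated correlation), with GINS1 at -1.14 (SE 0.07). Interferon-stimulated genes fell in 10, rose in 3 and did not pass in 14 of 27 cases, with 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0354, but adjusted p = 0.146 with an estimated correlation). IFIH1, a sensor of double-stranded RNA, fell by 1.14 (SE 0.16). NRF2 targets rose in 11 and fell in 3 of 21, or 12 and 3 when adjusted over the list alone (camera adjusted p = 0.0445, but adjusted p = 0.175 with an estimated correlation), with EPHX1 at 0.70 (SE 0.08) and the malic enzyme ME1 at -0.63 (SE 0.10). Haematopoietic and endothelial markers rose in 7 of 17 cases and 7 when adjusted over the list alone, with small sizes such as 0.40 (SE 0.08) for CD14 (camera adjusted p = 0.0317, but adjusted p = 0.146 with an estimated correlation).

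Of these 6 calls, 3 were lost when single arrays were left out and also under other settings. The interferon call was lost without double knockdown replicate 3 (adjusted p = 0.069) and the marker call without control replicate 2 (adjusted p = 0.055), and the NRF2 call was lost without control replicate 1 (adjusted p = 0.0694), without shJMJD2C replicate 2 (adjusted p = 0.051) and without double knockdown replicate 3 (adjusted p = 0.0691). After quantile normalization and after the loess correction the marker list was not called (adjusted p = 0.198 and 0.139), and its median fell from 0.18 to 0.10 in both. With the 28S level as a covariate the interferon, marker and NRF2 lists were not called (adjusted p = 0.0506, 0.0506 and 0.0662), and with the replicate block the NRF2 list was not (adjusted p = 0.0548). Among the brighter genes alone, the interferon list, with 10 of 27 members left, had a median of -0.28 (adjusted p = 0.341), the E2F list was not called with a median of -0.22 (adjusted p = 0.103), and neither was the histone list with 4 of 22 members left (adjusted p = 0.103). Over its settings the interferon median ran from -0.28 to -0.08 around -0.16. Over all their settings the adjusted p of the interferon, marker and NRF2 lists reached 0.341, 0.198 and 0.175.

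The 3 comparisons against the control share their control arrays, so their changes correlate even with no effect. Across genes, the changes with shJMJD2C and in the double knockdown correlated with r = 0.94 (covariance 0.152), against a simulated r of at most 0.522 and a simulated covariance of 0.00396 for unchanged groups. Of the genes tested, 1926 rose and 2316 fell in both, where independent lists give 559 and 608, and 10 went opposite ways. Changes with shJMJD2A and in the double knockdown correlated with r = 0.42 (covariance 0.0449, simulated r at most 0.518). In this pair 477 genes rose and 873 fell in both, where independent lists give 234 and 313, and 387 went opposite ways. The single knockdowns correlated with r = 0.30 (covariance 0.0368), below the simulated r but above the simulated covariance of 0.00395. They shared 472 rises and 822 falls, where independent lists give 291 and 337, and 568 genes went opposite ways. In all 3 comparisons 410 genes rose and 770 fell, where independent lists give 56.4 and 73.1. Genes are not independent replicates, and with 3 controls that could not be split, part of these excesses may come from the shared control arrays.

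Adding the JMJD2A hairpin to the JMJD2C hairpin changed few genes and by small amounts. Between the double knockdown and shJMJD2C, 445 genes rose and 371 fell, 17 and 32 of them by at least 1.5-fold and 0 and 5 by at least 2-fold. The 5 falls of that size were the calcium-binding CALB1 (-1.06, SE 0.08), KDM4A itself (-1.04, SE 0.11), the phosphodiesterase SMPDL3A (-1.03, SE 0.11), TMED5 (-1.02, SE 0.09) and NXT2 (-1.01, SE 0.10). The 5 largest rises were those of the activin subunit INHBA (0.69, SE 0.10), the spermine synthase SMS (0.68, SE 0.09), DZIP3 (0.66, SE 0.15), ANKRD2 (0.62, SE 0.06) and the sialic acid activating CMAS (0.62, SE 0.09), with n = 3 arrays per group. KDM4C differed by 0.12 (SE 0.09, adjusted p = 0.521).

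E2F and replication genes were higher with both hairpins than with shJMJD2C alone in 18 of 35 cases, or 20 when adjusted over the list alone, and none was lower (camera adjusted p = 1.21e-15, and adjusted p = 0.0123 with an estimated correlation). FEN1 and MCM6 each rose by 0.45 (SE 0.08 and 0.06). Mitotic genes rose in 10 of 34 cases, or 18 when adjusted over the list alone (camera adjusted p = 2.12e-11, but adjusted p = 0.0662 with an estimated correlation), with the kinesin KIF11 at 0.62 (SE 0.08). Immediate early genes fell in 8 of 30, or 9 when adjusted over the list alone (camera adjusted p = 9.19e-05, and adjusted p = 0.0286 with an estimated correlation), with CCN2 at -0.68 (SE 0.06) and MAFF at -0.47 (SE 0.09). NF-kB and inflammatory cytokine genes fell in 6 of 25, or 8 when adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.0356 with an estimated correlation), with the feedback inhibitor TNFAIP3 at -0.46 (SE 0.07) and IL6 at -0.41 (SE 0.06). Over the control, this list averaged -0.12, 0.05 and -0.13 in double knockdown replicates 1, 2 and 3, and 0.12, 0.09 and 0.08 with shJMJD2C. Replicate 2 thus showed little of the fall, though the list stayed called in all 21 other settings. NRF2 targets fell in 4 of 21, or 6 when adjusted over the list alone (camera adjusted p = 0.0112, but adjusted p = 0.121 with an estimated correlation), with HMOX1 at -0.46 (SE 0.06).

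The 816 genes called here became 497 without shJMJD2C replicate 2, and 440, 432 and 406 without double knockdown replicates 1, 2 and 3 (8 lists were called without the last of these), while array weights raised the count to 1604. The NRF2 call was lost without shJMJD2C replicate 3 (adjusted p = 0.0537), and the DZIP3 call without shJMJD2C replicate 2 (adjusted p = 0.0632) and without double knockdown replicate 3 (adjusted p = 0.0647), where over all settings their adjusted p reached 0.121 and 0.0679. The DZIP3 change itself ran from 0.29 to 0.77 over its settings.

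Adding the JMJD2C hairpin to the JMJD2A hairpin changed many genes. The double knockdown against shJMJD2A showed 2139 genes higher and 2403 lower, 421 and 809 of them by at least 1.5-fold. STEAP1, a metalloreductase, rose by 2.47 (SE 0.10), FN1 by 2.16 (SE 0.07), SCG2 by 2.14 (SE 0.12), CCN2 by 2.06 (SE 0.06) and HMGA2 by 1.95 (SE 0.07), with n = 3 arrays per group. The acetyltransferase KAT2B fell by 2.15 (SE 0.10), the adenylate cyclase ADCY9 by 2.12 (SE 0.10), ZNF226 by 1.99 (SE 0.13), CEP63 by 1.91 (SE 0.11) and the RNA-binding RBM47 by 1.88 (SE 0.09). KDM4C fell by 1.28 (SE 0.09), and KDM4A was higher by 0.56 (SE 0.11, adjusted p = 0.00127).

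Of the 7 lists called in that comparison, the mitotic and the immediate early list held with an estimated correlation. Mitotic genes fell in 32 of 34 cases, and 32 when adjusted over the list alone (camera adjusted p = 4.61e-17, and adjusted p = 0.0415 with an estimated correlation), with the kinase NEK2 at -1.22 (SE 0.12). Immediate early genes rose in 18 and fell in 2 of 30, with the same counts adjusted over the list alone (camera adjusted p = 7.88e-05, and adjusted p = 0.0415 with an estimated correlation), the feedback regulators SPRY2 and DUSP6 rising by 1.26 (SE 0.14) and 1.06 (SE 0.11). E2F and replication genes fell in 17 and rose in 3 of 35, with the same counts adjusted over the list alone, led by thymidylate synthase TYMS at -0.92 (SE 0.06). HIF targets rose in 12 and fell in 4 of 28, or 13 and 4 when adjusted over the list alone, with MXI1 at 1.76 (SE 0.06). NRF2 targets rose in 10 and fell in 1 of 21, unfolded protein response genes rose in 12 and fell in 5 of 29, and H3K9 factors fell in 8 and rose in 2 of 20, with the same counts adjusted over each list alone. These 5 lists had an adjusted p = 0.16 with an estimated correlation. The 28S and interquartile range differences stated for the JMJD2C hairpin lie between these groups too.

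The calls of the NRF2, unfolded protein response and H3K9 lists were lost without single arrays and under other settings. Only 4 lists were called without control replicate 1 and without double knockdown replicate 3, where the NRF2 list had adjusted p = 0.051 and 0.0668. The H3K9 list was lost without control replicates 1, 2 and 3 (adjusted p = 0.0516, 0.051 and 0.0554), without shJMJD2A replicates 2 and 3 (adjusted p = 0.061 and 0.065) and without double knockdown replicates 1, 2 and 3 (adjusted p = 0.0643, 0.0597 and 0.0567). The unfolded protein response list was lost without control replicates 1, 2 and 3 (adjusted p = 0.0521, 0.051 and 0.0574), without shJMJD2A replicates 1 and 3 (adjusted p = 0.0604 and 0.065) and without double knockdown replicate 3 (adjusted p = 0.0926). The H3K9 list was also not called after quantile normalization, after the loess correction or among the brighter genes alone (adjusted p = 0.13, 0.0863 and 0.179), and its median ran from -0.28 to -0.07 around -0.17. The unfolded protein response list was also lost among the brighter genes (adjusted p = 0.051). With the 28S level as a covariate, the H3K9, HIF, unfolded protein response and NRF2 lists were not called (adjusted p = 0.0619, 0.0542, 0.0903 and 0.0705). Over all settings the highest adjusted p of the NRF2, H3K9 and unfolded protein response lists were 0.16, 0.179 and 0.16.

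A direct comparison of the single knockdowns asked where the hairpins differ. With shJMJD2C against shJMJD2A, 2573 genes were higher and 2663 lower, 676 and 1168 by at least 1.5-fold. CCN2 was higher by 2.74 (SE 0.06), NXT2 by 2.63 (SE 0.10), FN1 by 2.56 (SE 0.07), STEAP1 by 2.48 (SE 0.10) and the oncofetal antigen TPBG by 2.32 (SE 0.07), with n = 3 arrays per group. KAT2B (-2.42, SE 0.10), ADCY9 (-2.40, SE 0.10), the annexin ANXA9 (-2.16, SE 0.10), ZNF226 (-2.15, SE 0.13) and CEP63 (-2.08, SE 0.11) were lower. KDM4C was lower by -1.40 and KDM4A higher by 1.60, as the hairpins' targets. With the 28S level as a covariate, a setting chosen after the data were seen, 3359 genes were called in place of 5236.

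Of 7 lists called between the single knockdowns, 3 held with an estimated correlation. Mitotic genes were lower in 32 and higher in 1 of 34 cases, with the same counts adjusted over the list alone (camera adjusted p = 6.71e-18, and adjusted p = 0.0312 with an estimated correlation). E2F and replication genes were lower in 24 and higher in 1 of 35, or 25 and 1 when adjusted over the list alone (adjusted p = 0.0312 with an estimated correlation), with FEN1 at -1.07 (SE 0.08). Immediate early genes were higher in 19 and lower in 2 of 30, or 20 and 2 when adjusted over the list alone (adjusted p = 0.028 with an estimated correlation), with SPRY2 at 1.35 (SE 0.14) and DUSP6 at 1.30 (SE 0.11). The other 4 were NRF2 targets (11 higher and 2 lower of 21, adjusted p = 0.105 with an estimated correlation), HIF targets (14 higher and 4 lower of 28, adjusted p = 0.186 with an estimated correlation), NF-kB and inflammatory genes (11 higher and 2 lower of 25, adjusted p = 0.157 with an estimated correlation) and H3K9 factors (2 higher and 12 lower of 20, adjusted p = 0.105 with an estimated correlation). Adjusted over each list alone, the counts were 11 and 2, 14 and 4, 11 and 2, and 2 and 12. The H3K9 list was not called after quantile normalization, among the brighter genes alone or after the loess correction (adjusted p up to 0.174), while its median stayed between -0.42 and -0.23 over all settings.

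The interaction measured by how much the joint change differed from the sum of the single changes on the log2 scale. It was above 0 in 1032 genes and below 0 in 738, and 412 and 215 of these differed by at least 1.5-fold (n = 3 arrays in each of 4 groups). HMGA2 had the largest positive interaction, 2.86 (SE 0.10): it fell by 2.74 with shJMJD2A, and the double knockdown was 1.95 above that level. Its mean in the double knockdown thus stayed below the control. An interaction larger than 1.95 also means that the HMGA2 mean was lower with shJMJD2C than in the control. CCN2 (2.70, SE 0.09), ELK3 (2.68, SE 0.17), TGM2 (1.92, SE 0.13) and the lipoprotein receptor LRP8 (1.75, SE 0.14) followed. The largest negative interactions were those of SERPINB13 (-2.53, SE 0.09), KRT5 (-2.14, SE 0.15), H4C8 (-2.09, SE 0.13), H1-2 (-2.09, SE 0.09) and H2AC6 (-1.99, SE 0.10). Neither target had a called interaction: the value was 0.21 (SE 0.12, adjusted p = 0.311) for KDM4C and 0.19 (SE 0.16, adjusted p = 0.507) for KDM4A.

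Of the 1770 genes with an interaction, 857 differed from the control in the same direction in all 3 comparisons, 566 of them lower and 291 higher. For each of these 857 the interaction had the opposite sign, so that the joint change was smaller than the sum. The control arrays enter the interaction with the sign opposite to that in the 3 comparisons. Selecting genes by these comparisons therefore favours the opposite sign, and the 857 are no separate evidence of a smaller joint change. Histone genes, which rose with each hairpin, had interactions below 0 in 12 of 22 cases, or 14 when adjusted over the list alone (camera adjusted p = 1.29e-12, and adjusted p = 0.00307 with an estimated correlation). Immediate early genes had interactions above 0 in 12 and below 0 in 1 of 30, or 14 and 1 when adjusted over the list alone (camera adjusted p = 2.51e-06, and adjusted p = 0.0112 with an estimated correlation). Mitotic genes had them above 0 in 12 and below 0 in 1 of 34, or 18 and 1 when adjusted over the list alone (adjusted p = 0.16 with an estimated correlation), with HMMR at 1.29 (SE 0.13). E2F and replication genes had them above 0 in 12 of 35, or in 14 with 1 below 0 when adjusted over the list alone (adjusted p = 0.0769 with an estimated correlation). The 14 measured neighbours of KDM4C on the short arm of its chromosome had 4 interactions above 0, or 6 when adjusted over the list alone (adjusted p = 0.0769 with an estimated correlation), with RANBP6 at 0.61 and PLGRKT at 0.60 (SE 0.10 each).

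For the 2645 genes other than KDM4A that were called with shJMJD2A, the change that the JMJD2A hairpin made on top of shJMJD2C was regressed on the change it made alone, through the origin. The slope was 0.108 (jackknife SE 0.0249 over arrays), and 0.126 (SE 0.0186) for the 147 that changed at least 2-fold. KDM4A itself kept 0.844 (SE 0.144) of its fall. CCN2 fell by 3.39 with shJMJD2A alone and by 0.68 on top of shJMJD2C.

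**Figure D3:**
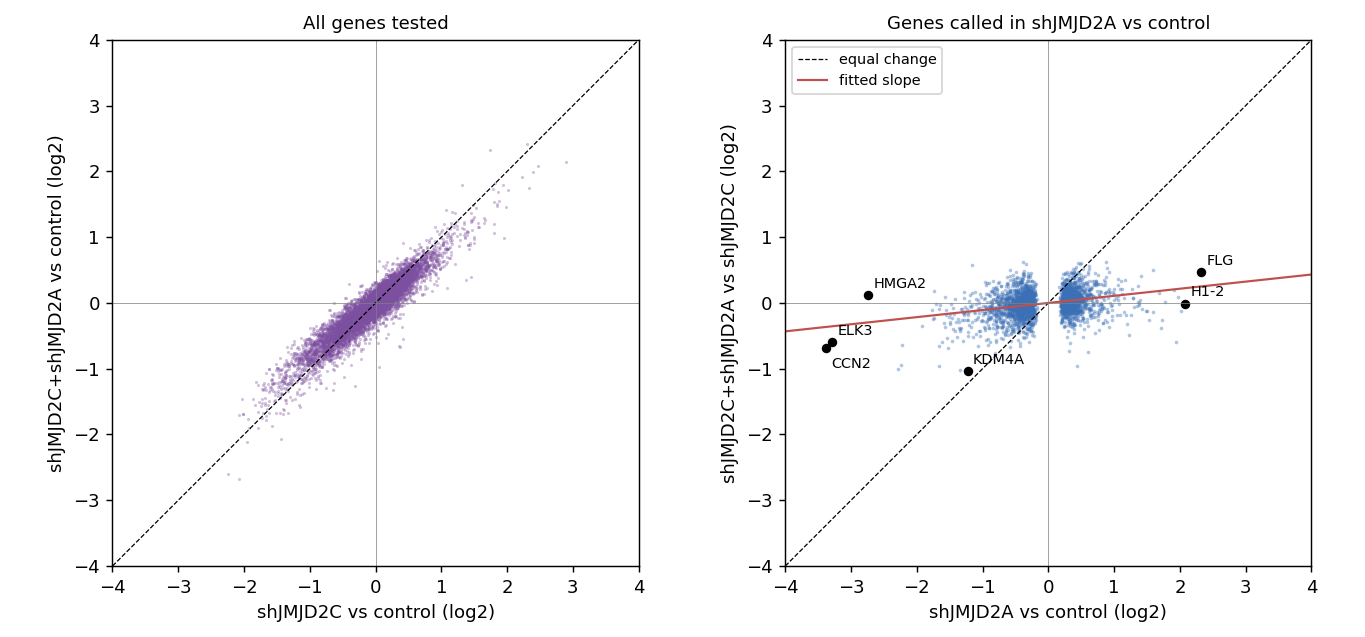
Left, log2 change in the double knockdown against that in shJMJD2C for all 11963 genes, with the line of equal change (dashed). Right, change from shJMJD2C to the double knockdown against the change with shJMJD2A alone, for genes called with shJMJD2A; the fitted line has a slope of 0.108 and KDM4A lies close to the line of equal change.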

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

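The first part weighs 3 patterns that stood out. Of its tests, the matched lists, the E2F comparison and the share of genes that differ from the control in all 3 groups were chosen after the result was seen; the others were written down before it.

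All 34 mitotic genes fell with shJMJD2C alone, and 31 of 34 in the double knockdown. None of 10000 random lists matched on signal had a median as low (0.01% once the observed list is counted in). The lowest matched median was -0.50 with shJMJD2C and -0.47 in the double knockdown, which argues against a signal-dependent compression of the arrays. With the 28S level as a covariate the list median with shJMJD2C stayed at -0.90. That value cannot decide about the ribosomal RNA content of the samples. Every array with the JMJD2C hairpin had more 28S signal than every array without it. In a model with group means the covariate is fitted on differences within groups only. The E2F and replication list fell too, which fewer dividing cells would give, with a median of -0.46 with shJMJD2C and a smaller one of -0.19 in the double knockdown, where 18 of 35 members fell and none rose and the list was not called with an estimated correlation (adjusted p = 0.158). Replication-dependent histone genes went the other way, rising in 13 of 22 cases with shJMJD2C and in 11 in the double knockdown. They rose in 13 of 22 cases with shJMJD2A as well. There the mitotic list (median -0.05) and the E2F list (median 0.09) were not called, so a histone rise also occurred without a called fall of these lists. Whether the histone rise with shJMJD2C is connected to their fall in those arrays was not tested. Whether loss of JMJD2C slows division, or the hairpin acts off target, stays open with 1 hairpin per gene, and neither cell numbers nor growth were analysed here.

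The response to the JMJD2A hairpin was much smaller on top of the JMJD2C hairpin. KDM4A kept a larger share of its change than the other genes did, by 0.736 (jackknife SE 0.151). That argues against a weaker knockdown of JMJD2A that the other genes follow in proportion to KDM4A RNA. Whether they do so was not tested and JMJD2A protein was not analysed here, so a weaker knockdown with another form of response cannot be judged. The KDM4A share is taken from the raised level with shJMJD2C, a rise that did not pass for the other KDM4A probe set. Against the control KDM4A fell by 0.67 in the double knockdown and by 1.23 with shJMJD2A. The difference was 0.56 (adjusted p = 0.00127), so a weaker knockdown may be part or all of the reason. Among 758 genes that were not called with shJMJD2C and changed by less than 0.25 there, the slope was still only 0.181 (SE 0.0259), which argues, for these genes alone, against having already moved as far as they can. The reason stays open, and off-target effects of the hairpins and competition between them were not tested.

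Genes with an interaction often differed from the control in all 3 knockdown groups. The lowest count of all interaction genes without 1 control array was 0.863 of the count with all arrays, and those that changed the same way in all 3 comparisons numbered 783, 693 and 745 without control replicates 1, 2 and 3, against 857 with all, which argues against 1 deviating control. These 857 are 48.4% of the interaction genes, and 282 of them showed no difference between any knockdown groups. That share has no value to set it against, because the comparisons and the interaction use the same control arrays. A scrambled control that stands apart from every knockdown cannot be told apart here from a response that both hairpins share and that saturates, since these genes were called with shJMJD2C and are not among the 758 above.

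Random regrouping was tried for each comparison. For the 6 comparisons of 3 against 3 arrays, only 1 of 10 splits, the real one, gave as many genes. Every other split gave at most 0, and with 10 splits no share below 0.05 can be reached. The other splits mix arrays of groups that differ, which puts that difference into the spread, so their low counts do not bear on chance. For the interaction, 3 of 100 splits of the 12 arrays, counting the real one, gave as many genes, the highest other count being 2214. These splits also mix the differences between groups into the contrast and the spread, so they cannot decide about the interaction.

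The interaction values below were picked out because the joint change differed from the sum of the single changes. This was so for 1032 genes above 0 and 738 genes below 0. The largest values above 0 were HMGA2 (2.86), CCN2 (2.70), ELK3 (2.68), TGM2 (1.92) and LRP8 (1.75), and below 0 SERPINB13 (-2.53), KRT5 (-2.14), H4C8 (-2.09), H1-2 (-2.09) and H2AC6 (-1.99). List medians were 0.21 for E2F and replication genes, 0.29 for mitotic genes, -0.48 for histone genes, 0.22 for immediate early genes and 0.26 for the neighbours of KDM4C on its chromosome. Over the settings the medians ran from -1.48 to -0.41 for histone genes, from 0.18 to 0.53 for the neighbours and from 0.19 to 0.37 for immediate early genes. The values farthest from 0 came from the brighter genes alone, which leave 4 of 22, 5 of 14 and 22 of 30 members.

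Other values were picked out because they come from probe sets outside the gene tests. The 28S ribosomal RNA probe set was higher by 0.63 in the arrays with the JMJD2C hairpin. Of 3151 probe sets without exactly 1 gene symbol, 1093 changed with shJMJD2C, 420 with shJMJD2A and 927 in the double knockdown.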

How the results depend on the processing

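Every comparison was repeated under the alternatives listed in the methods, and the cause of a change was not tested except where the setting itself makes it. A minimum of 1.5-fold, which removes small changes by construction, left 1734 (shJMJD2C), 587 (shJMJD2A), 1279 (double), 49 (double against shJMJD2C), 1230 (double against shJMJD2A), 1844 (shJMJD2C against shJMJD2A) and 627 (interaction) genes. Array weights gave 1604 genes for the double knockdown against shJMJD2C. That count ran from 406 without double knockdown replicate 3 to 875 without control replicate 2. The change of KDM4A with shJMJD2C ran from 0.31 to 0.42 when single arrays were left out, and from 0.30 to 0.58 over all 23 settings. With the 28S level as a covariate, chosen after the data were seen, shJMJD2C against shJMJD2A gave 3359 genes, and 3 lists were called in the double knockdown against the control and 3 against shJMJD2A.

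Lists depended on the test. With an estimated correlation 3 (shJMJD2C), 0 (double), 3 (double against shJMJD2C), 2 (double against shJMJD2A), 3 (shJMJD2C against shJMJD2A) and 2 (interaction) were called. The self-contained test fry, which asks another question, called 18, 19, 22, 13, 21, 17 and 15 in the order of the 7 comparisons. Among brighter genes only, 3, 5 and 2 were called against the control and 8 in the double knockdown against shJMJD2C, where quantile normalization called 9. Left-out arrays gave 4 to 8 lists for the double knockdown against shJMJD2C and 4 to 7 against shJMJD2A. Correlations of changes among brighter genes were 0.246 (single knockdowns), 0.943 (shJMJD2C and double) and 0.390 (shJMJD2A and double). With the mean of all probe sets, DST turned from 1.14 to -0.0281 with shJMJD2C (adjusted p = 0.682) and from 1.21 to -0.00542 in the double knockdown (adjusted p = 0.947).

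Replicate number as a block gave 5501, 2451, 4718, 638, 4382, 5067 and 1580 genes. For the double knockdown against shJMJD2C, the groups that met the rule for a pairing, the block changed the call of no list and of no gene named there. In the lists called there, counts of called members moved by less than 1.5 times (E2F genes 18 to 17, mitotic genes 10 to 8, NF-kB genes 6 to 5, NRF2 targets 4 to 3). Lists that were not called, with few called members, moved by as much or more in some cases. Higher cholesterol genes went from 2 to 1 and lower JmjC demethylases from 3 to 2. In the other pairs of groups, deviations of same-number arrays correlated from -0.328 to 0.199. Over all groups, 1 of 12 arrays was closest to one with its own number. It was double knockdown replicate 2, closest to shJMJD2C replicate 2 (0.125).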

Other observations

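Several stress and metabolic genes moved strongly inside lists that did not pass as a whole. With shJMJD2C the vasodilator peptide ADM rose by 1.47 (SE 0.06) while the mTOR inhibitor DDIT4 fell by 1.42 (SE 0.07), both being HIF targets. HERPUD1, a gene of protein degradation at the endoplasmic reticulum, rose by 0.99 (SE 0.07). With shJMJD2A the p53 targets GDF15 and ZMAT3 moved in opposite directions, at 1.22 (SE 0.08) and -1.07 (SE 0.11). The interaction of GDF15 was -1.71 (SE 0.12), and that of the interferon-stimulated RSAD2 was 1.65 (SE 0.14).

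The genomic span of a gene went with its change, a comparison made after the data were seen. Across 11955 genes the rank correlation of span and change was -0.175 with shJMJD2C, -0.131 with shJMJD2A and -0.187 in the double knockdown. Genes are not independent, so these are given as values only.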
